A study of Mus musculus with 8 samples.

How the data were processed

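Gene expression was measured on 8 Agilent 1-colour arrays of mouse small intestine, 2 per group, on 2 slides of 4 arrays each. Per the labels' protocols, RNA was extracted with Trizol and RNeasy, amplified and labelled with Cy3 by the Low Input Quick Amp kit. Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, and the probe coordinates are those of the mouse build mm9. The processed signal is, per the file headers, an intensity on a linear scale from which background was subtracted and which was detrended within the array, with no scaling between arrays. The series matrix holds the same deposited intensity values, equal to the processed signals with a ratio of 1 and so linear and uncentred, for spots well above background only, of which 375 to 878 per array have no value in it, 192 to 394 of these with an outlier or saturation mark. Its medians were 674, 728, 762 and 692 on slide 1 and 743, 849, 814 and 816 on slide 2, in the order 0 Gy saline, 8 Gy saline, FGF1 and FGF1/CPP-C. How the authors normalised between arrays for their own comparisons is not given in the sources used here.

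The log2 of the processed signal was taken, and each array's 75th percentile of it was subtracted. A floor of -6.95 on this scale, the same on every array, was set because some processed signals were negative. It was chosen once negative signals had been found. Control spots, 1377 per array, and spots with an outlier mark were left out, and saturated spots were kept. Spots of 1 probe were averaged, 43020 spots giving 39429 probes. Of these, 28330 were named through an accession in a RefSeq table of GRCm38.p6, from which only names were taken, 2378 through the symbol in the array files, and 8721 kept the name in the array files. A probe was kept if it was well above background on both arrays of at least 1 group, which 27538 probes were, and each gene was represented by its brightest probe. This gave 21807 genes, 16909 of them with a RefSeq name, and 4693 genes had several probes. Probes of a gene can disagree, and the mean of the kept probes was an alternative.

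Groups were compared with limma 3.58.1 in R 4.3.3, reading with the package data.table (version 1.17.8), fitting the 4 group means to all 8 arrays, which left 4 residual degrees of freedom, with Benjamini-Hochberg adjustment over all genes of a comparison and an adjusted p under 0.05 as the threshold. With 2 arrays per group a single gene's exact permutation test cannot go below p = 0.333, and chance alone separates 2 against 2 values in 33.3% of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Of 46 gene lists, those with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. No list call held with an estimated correlation in any of the 6 comparisons. A count given as adjusted over the list alone adjusts p over the members of that list.

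The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each of the first 4 comparisons, the 10 genes per direction with the largest fold change among those that passed, did not overlap between the groups and had an established symbol, filled to 5 by smallest p among genes at least 2-fold apart. In the last 2 comparisons it took 5 per direction with no fill. It also took p53, stem cell, FGF, immediate early and proliferation genes named in advance, and for each list up to 4 members that passed or the 2 of smallest p. Of the genes named in advance, Spry4 was not measured. Not every gene the rule took is described, and 2 are not reported here. Lists for stomach antrum, Brunner glands, Hox genes, alpha-defensins and acute-phase proteins were drawn up after the values had been seen.

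The test was tried on simulated data of 21535 genes with 200 changed. For 8 Gy saline against 0 Gy saline it recovered 58.2% of 67 genes changed 2-fold, 88.1% of 67 changed 4-fold and 97.0% of 66 changed 8-fold, with 7 false calls among 21309. For FGF1 against 8 Gy saline it recovered 55.2%, 92.5% and 95.5%, for FGF1/CPP-C against 8 Gy saline 71.6%, 88.1% and 100%, and for FGF1/CPP-C against FGF1 59.7%, 91.0% and 90.9%. The simulated noise was independent between genes, had the fitted spread in every group and held no shift shared by the genes of an array. With 200 genes changed, the adjusted threshold was also easier to reach than where few genes change. Recovery in the real arrays may therefore be lower. Paqr9 and Aqp8, described below, were over 4-fold apart in FGF1/CPP-C against FGF1 and did not pass.

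The alternatives were quantile normalisation, normexp background correction with an offset of 50, the series matrix values, 2 other filters on dim probes, the mean of a gene's probes, a fit to the 2 groups compared alone, the replicate number as a block, which is the slide, moderation with trend and robust, thresholds with a 2-fold minimum, and leaving out each array in turn. After the data had been seen, 3 were added: leaving out the 3 arrays with high antrum transcripts, the antrum level as a covariate, and the antrum and acinar levels as 2 covariates.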

Results

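Gene expression was measured in the small intestine of female BALB/cA Jcl mice aged 8 weeks, 4 h after exposure to carbon ions, a particle beam used in radiotherapy. The design text names the segment as jejunum. Mice received an intraperitoneal injection of saline, of FGF1 (fibroblast growth factor 1, which signals through FGF receptors) or of FGF1/CPP-C, a chimeric protein built on FGF1, and 12 h of pretreatment preceded the irradiation. There were 4 groups of 2 arrays each: saline with 0 Gy, saline with 8 Gy, FGF1 with 8 Gy and FGF1/CPP-C with 8 Gy. Each array was a 1-colour Agilent array hybridised with Cy3-labelled RNA, and replicate 1 of every group lay on slide 1 and replicate 2 on slide 2.

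The 75th percentile of the processed signal ranged from 1735 to 2165 intensity units over the 8 arrays, and from 68.2% to 72.5% of the probes were well above background. The 2 arrays of a group correlated across genes with r between 0.982 (8 Gy saline) and 0.993 (8 Gy FGF1/CPP-C), and genes are not independent replicates. The number of arrays, 2 per group, limits the precision of every value below. All log2 fold changes are given ± the standard error of the limma fit. The labels do not say whether the 2 arrays of a group came from separate animals, so the limma p-values measure only the spread between these arrays, which may be technical. Camera at the preset correlation sets the genes of a list against all other genes. Its p-values therefore measure mainly the spread across genes and can be small with few arrays.

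Transcripts of neighbouring organs were high in single arrays. The median of 13 measured stomach antrum markers, a list drawn up after the values had been seen, was 0.77, 1.95 and 1.00 on the normalised log2 scale in 0 Gy saline replicate 1, 8 Gy saline replicate 2 and FGF1 replicate 1. In the other 5 arrays it lay between -5.64 and -3.98. The median of the 13 measured pancreatic acinar genes, digestive enzymes of the exocrine pancreas, was 5.82 in 0 Gy saline replicate 1 and 3.1 in 8 Gy saline replicate 2, -1.25 in FGF1/CPP-C replicate 1, and -5.20 to -3.65 in the other 5 arrays. Absorptive enterocyte genes lay between 5.35 and 6.05 in all 8 arrays. Their median was lowest in the 3 arrays with high antrum markers (5.79 in 0 Gy saline replicate 1, 5.35 in 8 Gy saline replicate 2 and 5.59 in FGF1 replicate 1). It was 5.89 to 6.05 in the other 5.

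**Figure D1:**
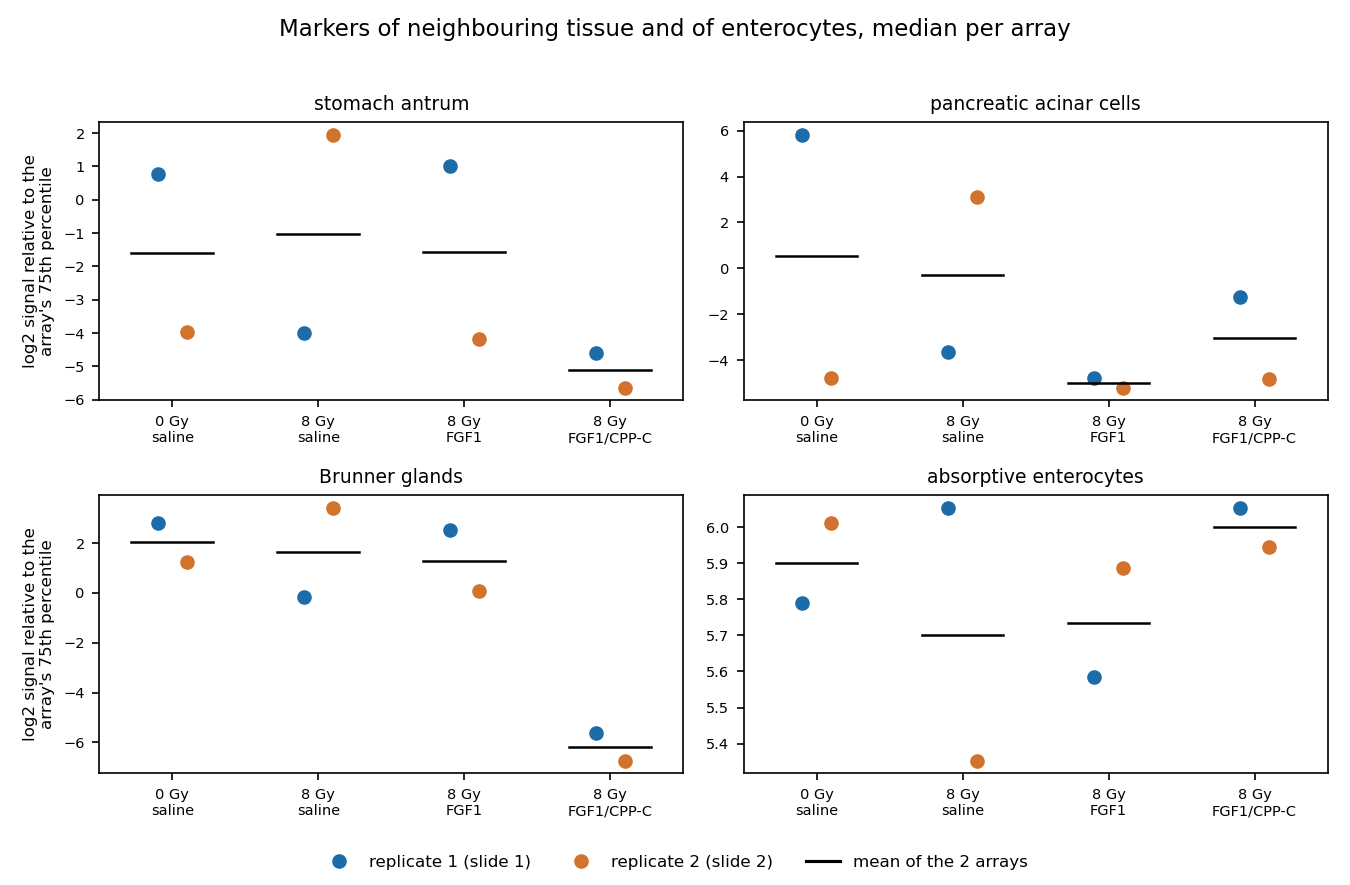
Median normalised signal per array (y axis, log2 signal relative to the array's 75th percentile) of 4 marker lists in the 4 groups (x axis); points are single arrays coloured by replicate and slide, and bars are the mean of the 2 arrays. The antrum median is above 0 in 3 arrays, the acinar median is above 0 in 2 arrays, the Brunner gland median is -5.63 and -6.74 in the FGF1/CPP-C arrays, and the enterocyte median spans 5.35 to 6.05.

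The first comparison, 8 Gy saline against 0 Gy saline, asked how the tissue responded to carbon ions alone. Target genes of the DNA damage regulator p53 shifted upward, 15 of 30 passing, and genes of mitosis downward, 7 of 27 passing. Neither list was called with an estimated correlation between genes (adjusted p = 0.0813 and 0.412). Gdf15, a stress-induced cytokine and p53 target, was 48.0-fold higher in the irradiated arrays (log2 fold change 5.58 ± 0.30, limma adjusted p = 0.00491). Phlda3, a p53 target that restrains Akt, was 15.8-fold higher (3.99 ± 0.22, limma adjusted p = 0.00491), and cyclin B2, Ccnb2, which drives entry into mitosis, was 2.99-fold lower (-1.58 ± 0.20, limma adjusted p = 0.0482). Of 21725 genes tested, 89 changed at an adjusted p under 0.05, 68 higher and 21 lower, and 2679 had an unadjusted p under 0.05, 1062 higher and 1617 lower, where about 1086 would by chance.

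Of the 30 measured p53 target genes, 15 rose and none fell, and 21 rose when adjusted over the list alone. The list shifted upward with a median log2 fold change of 1.29, 1.11 on slide 1 and 1.5 on slide 2 (camera adjusted p = 1.36e-31). The adjusted p was 0.0813 with an estimated correlation and 0.00130 with fry, which asks only whether the genes of a list move on balance in 1 direction. Psrc1, which encodes a p53-regulated spindle protein, rose by 2.84 ± 0.14 and Ccng1, cyclin G1, by 2.72 ± 0.20 (limma adjusted p = 0.00491 and 0.0167). Mdm2, the ubiquitin ligase that degrades p53, rose by 1.11 ± 0.14 (adjusted p = 0.0465), and Trp53inp1, a p53-induced stress protein, rose by 1.29 ± 0.12 (adjusted p = 0.0249). Cdkn1a, the cell cycle inhibitor p21, did not pass over all genes (0.87 ± 0.12, adjusted p = 0.0611), nor did the pro-apoptotic gene Bbc3 (1.29 ± 0.24, adjusted p = 0.126). Among the 19 measured pro-apoptotic genes, 2 rose, the death receptor gene Tnfrsf10b (1.64 ± 0.15, adjusted p = 0.0249) and the mitochondrial pore former Bax (1.43 ± 0.12, adjusted p = 0.0188), and 3 were higher and 1 lower when adjusted over the list alone. That list as a whole did not pass (median 0.11, camera adjusted p = 0.0594).

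All 27 measured mitosis genes had a negative fold change, 7 of them fell, and 25 fell when adjusted over the list alone. The median was -0.78, -0.64 on slide 1 and -0.90 on slide 2 (camera adjusted p = 3.82e-25, fry adjusted p = 0.0107, adjusted p = 0.412 with an estimated correlation). Besides Ccnb2, the centrosome kinase gene Nek2 fell by 1.28 ± 0.10, the spindle checkpoint gene Bub1b by 1.17 ± 0.14 and the centromere histone gene Cenpa by 1.14 ± 0.11 (limma adjusted p = 0.0167, 0.0437 and 0.0249). Ccnb1, the partner cyclin of Cdk1, also fell (-1.13 ± 0.13, adjusted p = 0.0381), while the proliferation marker Mki67 did not pass (-0.78 ± 0.12, adjusted p = 0.0819). DNA replication genes moved the other way, with 19 of 27 positive and a median of only 0.14, 0.26 on slide 1 and 0.03 on slide 2 (camera adjusted p = 0.00107, adjusted p = 0.728 with an estimated correlation). None of them passed over all genes and 3 were higher when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, had 1.05 ± 0.14, adjusted p = 0.0565, and the replication licensing factor Cdt1 0.61 ± 0.11, adjusted p = 0.129.

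**Figure D2:**
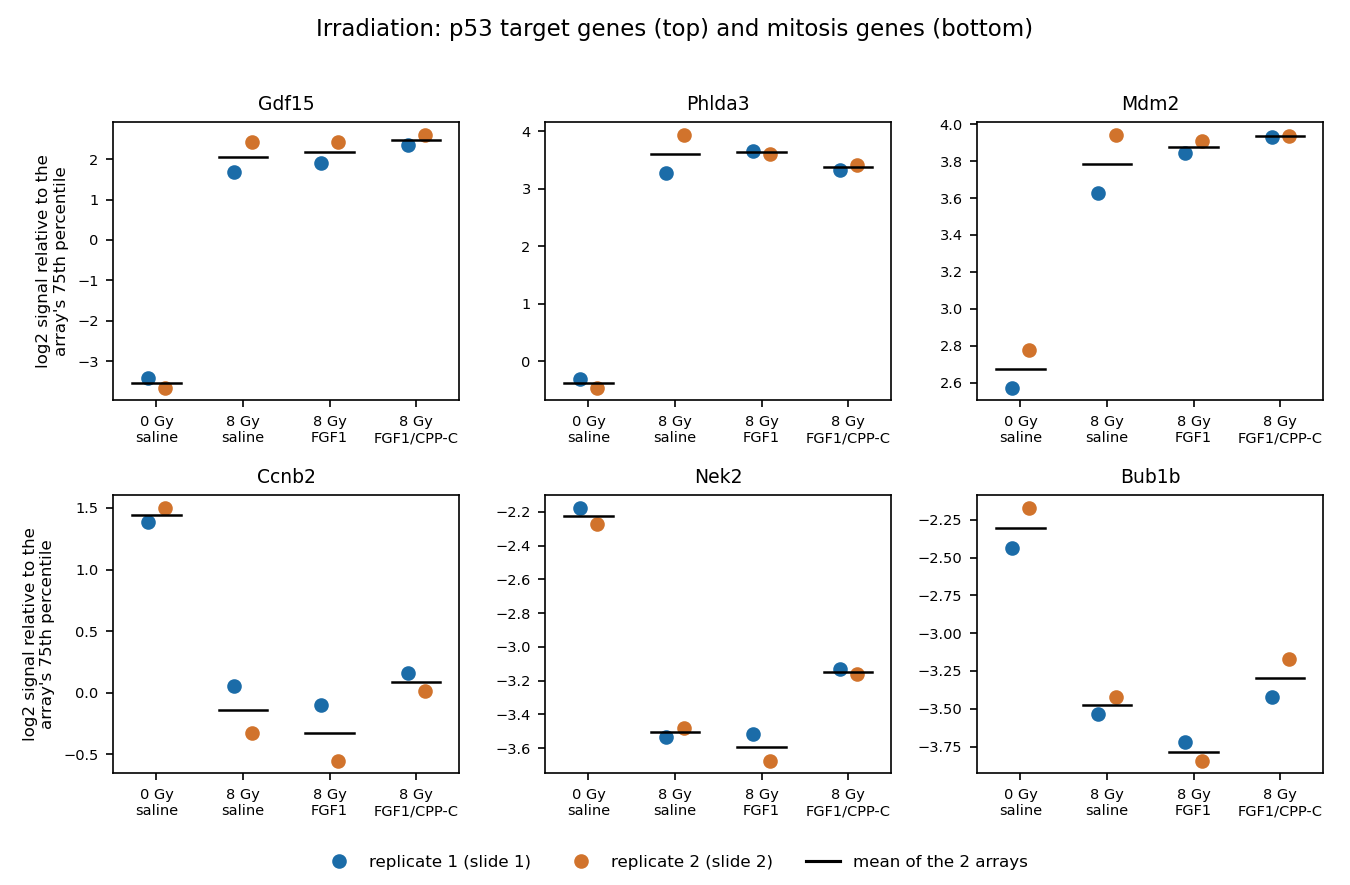
Normalised signal (y axis, log2 signal relative to the array's 75th percentile) of 3 p53 target genes and 3 mitosis genes in the 4 groups (x axis); points are single arrays coloured by replicate and slide, and bars are the mean of the 2 arrays. In all 6 panels the 2 unirradiated arrays lie apart from the 6 irradiated ones, with Gdf15 48.0-fold higher and Nek2 2.44-fold lower in 8 Gy saline than in 0 Gy saline.

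Other genes that rose by the largest amounts were the phospholipase gene Plcd4 (at least 7.31-fold), Tnfsf4, the OX40 ligand of T cell costimulation (at least 6.71-fold), Ddias, an apoptosis suppressor induced by DNA damage (2.70 ± 0.26), the glucocorticoid-induced chaperone gene Fkbp5 (2.65 ± 0.32), Inka2 (2.65 ± 0.31) and the keratin gene Krt15 (2.52 ± 0.28), with limma adjusted p from 0.00491 to 0.0437. Plcd4 and Tnfsf4 were not well above background without irradiation. For such genes the fold is a bound, the bright group's mean against the higher, per array, of the lowest signal well above background and the gene's own signal. The largest falls belonged to Cyp1a1, a xenobiotic-metabolising enzyme (5.03-fold lower, -2.33 ± 0.19, adjusted p = 0.0185), and Sfrp5, a secreted Wnt antagonist (-2.11 ± 0.18, adjusted p = 0.0188). Sele, the endothelial adhesion molecule E-selectin, was at least 3.87-fold lower and not well above background after irradiation (adjusted p = 0.0313). Further genes that fell were the cell cycle genes Cdkn3 (-1.53 ± 0.13), Aspm (-1.40 ± 0.15) and Prr11 (-1.21 ± 0.12) and the Wnt pathway gene Frat2 (-1.32 ± 0.14), with limma adjusted p from 0.0213 to 0.0299. In the mouse build mm9 that the array files use, the probe of Gdf15 lies on chromosome 8 at 73153293 to 73153352, that of Phlda3 on chromosome 1 at 137665642 to 137665701, that of Ccnb2 on chromosome 9 at 70255671 to 70255730 and that of Cyp1a1 on chromosome 9 at 57551535 to 57551594.

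FGF and ERK feedback targets shifted upward (median 0.32, 0.33 on slide 1 and 0.42 on slide 2). For FGF and ERK feedback targets camera gave adjusted p = 6.00e-05, and adjusted p = 0.530 with an estimated correlation. Of 18 measured, 1 rose, the ETS factor Etv4 (0.98 ± 0.11, adjusted p = 0.0360), and 5 rose when adjusted over the list alone. Dusp6 and Etv5, readouts of FGF signalling, had 0.33 ± 0.29 and 0.23 ± 0.31 (limma adjusted p = 0.727 and 0.824). Fgf1 itself had -0.48 ± 0.12 and the receptor genes Fgfr1, Fgfr2, Fgfr3 and Fgfr4 had -0.03 ± 0.15, -0.19 ± 0.09, -0.11 ± 0.15 and 0.02 ± 0.15, none of which passed (limma adjusted p = 0.223, 0.965, 0.481, 0.819 and 0.968). Immediate early genes shifted upward (median 0.16, 0.24 on slide 1 and 0.13 on slide 2), with Egr1 at 1.09 ± 0.51, adjusted p = 0.465, Fos at -0.06 ± 0.34, adjusted p = 0.964 and Myc at 0.44 ± 0.15, adjusted p = 0.331, and none of the 18 passed by either adjustment. For immediate early genes camera gave adjusted p = 0.0357, and adjusted p = 0.552 with an estimated correlation. Smaller upward shifts were called for ribosome biogenesis (median 0.10, 0.08 on slide 1 and 0.12 on slide 2), where Utp20 of the small-subunit processome rose (0.94 ± 0.11, adjusted p = 0.0381), and for the Notch pathway (median 0.11, 0.15 on slide 1 and 0.19 on slide 2), where the feedback gene Nrarp had 0.97 ± 0.16, adjusted p = 0.102. For ribosome biogenesis and Notch pathway, in this order, camera gave adjusted p = 0.0210 and 0.0169. The adjusted p for ribosome biogenesis and Notch pathway was 0.683 and 0.505 with an estimated correlation. Ribosome biogenesis had 1 gene higher when adjusted over the list alone, and the Notch pathway 3 higher and 1 lower.

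Among cell type lists, markers of T cells and intraepithelial lymphocytes were lower (median -0.61, -0.21 on slide 1 and -1.0 on slide 2), with 15 of 17 negative, none passing over all genes and 1 when adjusted over the list alone. For T cells and intraepithelial lymphocytes camera gave adjusted p = 6.00e-05, and adjusted p = 0.683 with an estimated correlation. Cd8b1, a CD8 chain, had -1.08 ± 0.19, adjusted p = 0.120, and Gzmb, granzyme B, -1.05 ± 0.30, adjusted p = 0.250. Mast cell genes were lower (median -0.97, -1.49 on slide 1 and -0.07 on slide 2), none over all genes and 3 when adjusted over the list alone, among them the protease gene Mcpt4 (-1.53 ± 0.24, adjusted p = 0.0905). For mast cells camera gave adjusted p = 0.0167, and adjusted p = 0.683 with an estimated correlation. Cholesterol synthesis genes were lower (median -0.24, -0.06 on slide 1 and -0.43 on slide 2), with 1 when adjusted over the list alone and Fdps at -0.61 ± 0.09, adjusted p = 0.0866. For cholesterol synthesis camera gave adjusted p = 0.00107, and adjusted p = 0.810 with an estimated correlation. Macrophage and dendritic cell genes were slightly lower (median -0.17, -0.09 on slide 1 and -0.39 on slide 2), and that call was lost with the slide as a block (adjusted p = 0.0988). For macrophages and dendritic cells camera gave adjusted p = 0.0467, and adjusted p = 0.853 with an estimated correlation. Adipocyte genes (median 0.50, 0.45 on slide 1 and 0.68 on slide 2) and regeneration genes (median 0.37, -0.28 on slide 1 and 1.16 on slide 2) were shifted upward, with 0 and 2 genes when adjusted over the lists alone. For mesenteric adipocytes and regeneration genes, in this order, camera gave adjusted p = 0.0167 and 0.00712. The adjusted p for mesenteric adipocytes and regeneration genes was 0.505 and 0.683 with an estimated correlation. The regeneration members Areg and Ereg, ligands of the EGF receptor, had 1.32 ± 0.26 and 0.99 ± 0.22 (limma adjusted p = 0.133 and 0.183). The regeneration shift had opposite signs on the 2 slides, and replicate 2 of 8 Gy saline is one of the arrays with high antrum and acinar transcripts. Crypt base stem cell genes did not pass (median -0.10, camera adjusted p = 0.542), with Lgr5 at -0.45 ± 0.19, adjusted p = 0.421 and Olfm4 at -0.47 ± 0.40, adjusted p = 0.716, nor did absorptive enterocytes (median 0.05) or double-strand break repair genes (median -0.00).

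With the slide as a block, which is also the replicate number, 37 genes changed, 30 higher and 7 lower, and 34 of them were among the 89, while within a slide each group has 1 array and no test can be made. Besides the estimated correlation and fry, 15 alternatives were run on the lists, and of the 13 lists called only p53 targets, mitosis and T cells kept their call in all. The T cell median was -0.29 without 8 Gy saline replicate 2. Macrophages lost their call in 11 of the 15. Mast cells lost theirs without 8 Gy saline replicate 1 (median -0.36, adjusted p = 0.444), without 0 Gy saline replicate 1 (adjusted p = 0.0639) and with the series matrix values (adjusted p = 0.0824). Adipocytes lost theirs with the series matrix values (adjusted p = 0.754) and without 8 Gy saline replicate 2 (adjusted p = 0.0775). Leaving out that array also ended the calls of regeneration genes (median -0.17, adjusted p = 0.742), the Notch pathway, ribosome biogenesis and immediate early genes. DNA replication (median 0.08, adjusted p = 0.0750), ribosome biogenesis and immediate early genes lost theirs without 0 Gy saline replicate 1, and cholesterol synthesis (median -0.15, adjusted p = 0.106) and the Notch pathway without replicate 2. Without the 3 arrays with high antrum transcripts, a choice made after the values were seen, those of FGF and ERK feedback targets (median 0.18), regeneration genes, the Notch pathway, ribosome biogenesis and immediate early genes were lost. The medians of the Notch pathway (0.14) and immediate early genes (0.18) were then no smaller than with all arrays. Immediate early genes also lost theirs with quantile normalisation and ribosome biogenesis with antrum and acinar levels as 2 covariates. Lists that had not passed were called in some alternatives. Crypt base stem cells were lower without 8 Gy saline replicate 2 (median -0.47, adjusted p = 0.0107) and without the 3 arrays (median -0.42, adjusted p = 0.00250), and absorptive enterocytes higher without 8 Gy saline replicate 2 (median 0.30, adjusted p = 0.00110) and without 0 Gy saline replicate 2 (median 0.16, adjusted p = 0.0389). Pro-apoptotic genes were higher with the slide as a block (adjusted p = 0.0381), with normexp (adjusted p = 0.0235), without 0 Gy saline replicate 2 (adjusted p = 0.0218) and without 8 Gy saline replicate 2 (median 0.25, adjusted p = 0.00941). Without either 0 Gy saline array, 0 genes passed, and without any other single array from 12 to 43 did.

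The second comparison, 8 Gy FGF1 against 8 Gy saline, asked what FGF1 pretreatment changed in the irradiated intestine. By limma, 0 of 21740 genes passed, 380 (219 higher, 161 lower) had an unadjusted p under 0.05 where about 1087 would by chance, and the smallest adjusted p was 0.665. With the slide as a block 0 genes passed, with the mean of a gene's probes 2 did, and 52 genes had an unadjusted p under 0.05 and at least a 2-fold difference. As a list, interferon response genes were higher after FGF1, with 25 of 26 positive (median 0.38, 0.12 on slide 1 and 0.58 on slide 2). For interferon response camera gave adjusted p = 1.43e-12, and adjusted p = 0.801 with an estimated correlation. Oas2 and Oasl2, of the antiviral oligoadenylate synthetase family, had 0.80 ± 0.24 and 0.65 ± 0.20 (limma adjusted p = 1.00 and 1.00), and none of the list passed by either adjustment.

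The genes with the smallest p among those at least 2-fold apart, none of which passed, included S100a8 and S100a9, the subunits of the neutrophil protein calprotectin, with 2.37 ± 0.26 and 2.54 ± 0.34 (limma adjusted p = 0.702 and 1.00). B3galt5, a galactosyltransferase gene, had 1.59 ± 0.25, Lrrc4 1.40 ± 0.28 and the small proline-rich gene Sprr2f 1.05 ± 0.21. On the lower side were the adipocyte hormone genes Retn (at least 12.6-fold lower) and Adipoq (at least 11.1-fold lower), the carbonic anhydrase gene Car3 (-4.29 ± 0.72), the Wnt antagonist Dkk4 (at least 2.06-fold lower) and Trim71 (at least 2.38-fold lower). All of these except Car3 on the lower side were not well above background after FGF1.

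The p53 target list had a median of -0.01, 0.15 on slide 1 and -0.15 on slide 2 (camera adjusted p = 0.996), with Mdm2 at 0.09 ± 0.14, Bax at 0.02 ± 0.12 and Cdkn1a at 0.14 ± 0.12. FGF and ERK feedback targets did not pass (median -0.08, camera adjusted p = 0.125), with Dusp6 at 0.34 ± 0.29, Etv5 at -0.22 ± 0.31 and Egr1 at -0.37 ± 0.51. Mitosis genes were slightly lower, 26 of 27 negative (median -0.15, -0.13 on slide 1 and -0.18 on slide 2), as were DNA replication genes (median -0.06, -0.13 on slide 1 and 0.01 on slide 2), none of either list passing by either adjustment. For mitosis and DNA replication, in this order, camera gave adjusted p = 7.68e-09 and 0.00766. For mitosis and DNA replication the adjusted p was 0.801 with an estimated correlation. Mki67 had -0.15 ± 0.12, and the stem cell genes Lgr5 and Olfm4 0.32 ± 0.19 and -0.30 ± 0.40.

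Adipocyte genes were lower (median -0.27, -0.42 on slide 1 and -0.43 on slide 2), none over all genes and 6 when adjusted over the list alone. For mesenteric adipocytes camera gave adjusted p = 1.12e-09, and adjusted p = 0.133 with an estimated correlation. The list, which holds Retn, Adipoq and Car3, had means of -0.88 and -1.10 in the 8 Gy saline arrays. They were -1.46 and -1.94 in 0 Gy saline and -2.75 to -2.30 in the pretreated arrays. Whether the samples differed in the amount of mesenteric fat was not tested. Pancreatic acinar genes were lower in all 13 (median -3.82, -0.24 on slide 1 and -7.56 on slide 2), beside the high acinar level of 8 Gy saline replicate 2. For pancreatic acinar cells camera gave adjusted p = 0.000203, and adjusted p = 0.801 with an estimated correlation. Smooth muscle (median -0.24, with -0.08 and -0.44 on the slides), fibroblast (median -0.19, with 0.13 and -0.34 on the slides) and regeneration genes (median -0.26, with 0.21 and -0.71 on the slides) were lower. For smooth muscle, fibroblasts and stroma and regeneration genes, in this order, camera gave adjusted p = 5.05e-07, 0.00766 and 0.0112. For smooth muscle and the other lists just named the adjusted p was 0.801 with an estimated correlation. Macrophage and dendritic cell genes were higher (median 0.22, 0.03 on slide 1 and 0.36 on slide 2), with Adgre1, the macrophage marker F4/80, at 0.63 ± 0.15. For macrophages and dendritic cells camera gave adjusted p = 0.00164, and adjusted p = 0.801 with an estimated correlation. Neutrophil genes were higher (median 0.09, 0.09 on slide 1 and 0.25 on slide 2), with 2 when adjusted over the list alone. For neutrophils camera gave adjusted p = 0.00480, and adjusted p = 0.801 with an estimated correlation. A further 5 lists were called upward, junction genes (median 0.11), Paneth cells (0.14), glycolysis and hypoxia (0.10), absorptive enterocytes (0.13) and pro-apoptotic genes (0.10), with camera adjusted p from 0.00766 to 0.0299 and adjusted p from 0.801 to 0.938 with an estimated correlation. No gene of these 5 lists passed by either adjustment.

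Of the 15 list calls only those of interferon response and mitosis were kept in all 15 alternatives other than fry and the estimated correlation. All 15 calls were lost with fry (adjusted p = 0.991 for interferon response and for mitosis) and with an estimated correlation. The slide as a block ended those of absorptive enterocytes and pro-apoptotic genes (adjusted p = 0.0529 for both). The series matrix values kept 9 and lost adipocytes (median -0.17, adjusted p = 0.351), acinar cells, neutrophils, Paneth cells, regeneration and pro-apoptotic genes. Without 8 Gy saline replicate 2 only 4 were kept, interferon response (median 0.18), mitosis, DNA replication and adipocytes. Fibroblasts were then called in the other direction (median 0.10), and the medians of neutrophils (-0.08), macrophages (-0.00), junction genes (-0.02), glycolysis and hypoxia (-0.00), regeneration genes (0.24) and enterocytes (-0.13) turned sign. Without 8 Gy saline replicate 1 the DNA replication call was lost (median -0.00, adjusted p = 0.661). Without FGF1 replicate 1 those of macrophages, neutrophils, fibroblasts, DNA replication, Paneth cells and pro-apoptotic genes were. Without FGF1 replicate 2 it was those of junction genes, regeneration, glycolysis and hypoxia, enterocytes and pro-apoptotic genes. Without the 3 arrays with high antrum transcripts 3 were kept, interferon response, mitosis and adipocytes, and with antrum and acinar levels as 2 covariates DNA replication and glycolysis and hypoxia besides. The p53 target list, not called in the main fit, was called lower without 8 Gy saline replicate 1 (median -0.14, adjusted p = 0.00987) but higher without replicate 2 (median 0.12, adjusted p = 0.00161) and without the 3 arrays (median 0.10, adjusted p = 0.0235). FGF and ERK feedback targets were called lower without 8 Gy saline replicate 1 (median -0.18, adjusted p = 0.00379), and crypt base stem cells higher without replicate 2 (median 0.25, adjusted p = 0.00741).

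The third comparison, 8 Gy FGF1/CPP-C against 8 Gy saline, asked the same of the chimeric protein. Both FGF1/CPP-C arrays may hold another segment of intestine, as described under the other observations. An effect of the protein cannot be told apart from such a difference. Of 21740 genes, 2 passed, both lower after FGF1/CPP-C and both of gastric-type mucous glands. Tff2, a trefoil peptide of mucous neck cells and Brunner glands, was at least 2.91e+04-fold lower (adjusted p = 0.000216 by limma) and not well above background. Gkn3, a gastrokine gene, was 672-fold lower (-9.39 ± 0.40, adjusted p = 0.00419 by limma). The probe of Gkn3 lies on chromosome 6 at 87333375 to 87333434 (mm9). In the 6 arrays of the other groups the 2 genes were high, also where antrum markers were low, while the Brunner gland list, drawn up after the values had been seen, had a median of -6.59, -1.64 on slide 1 and -9.94 on slide 2.

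In all, 2591 genes, 1601 higher and 990 lower, had an unadjusted p under 0.05 where about 1087 would by chance. Genes that did not pass but had the smallest p among those at least 2-fold apart were the lactate transporter gene Slc5a12 (at least 16.5-fold higher, adjusted p = 0.0971), Paqr9 (2.40 ± 0.21, adjusted p = 0.0971), the vomeronasal receptor gene Vmn1r132 (at least 2.05-fold higher), the homeobox gene Hoxc5 (at least 3.07-fold higher) and S100a8 (2.33 ± 0.26). On the lower side were the carboxylesterase gene Ces1b (-1.51 ± 0.12, adjusted p = 0.0887), the endopeptidase gene Kel (at least 3.71-fold lower) and the dicarboxylate transporter gene Slc13a3 (at least 3.19-fold lower).

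Interferon response genes were higher, 25 of 26 positive (median 0.62, 0.56 on slide 1 and 0.70 on slide 2), none over all genes and 16 when adjusted over the list alone, with Oasl2 and Ifit3 at 1.13 ± 0.20 and 0.89 ± 0.18 (limma adjusted p = 0.230 and 0.273). For interferon response camera gave adjusted p = 2.44e-11, and adjusted p = 0.621 with an estimated correlation. Lymphocyte markers were higher: T cells (median 0.68, 0.22 on slide 1 and 1.04 on slide 2), with Cd8b1 and Cd3d at 0.78 ± 0.19 and 0.86 ± 0.22, and B cells (median 1.22, 0.33 on slide 1 and 1.91 on slide 2), with Cd72 and Spib at 1.22 ± 0.14 and 1.33 ± 0.38. For T cells and intraepithelial lymphocytes and B cells, in this order, camera gave adjusted p = 2.43e-05 and 0.00112. For T cells and intraepithelial lymphocytes and B cells the adjusted p was 0.621 with an estimated correlation. Of the T and B cell genes, 3 and 1 were higher when adjusted over the lists alone. Macrophage and dendritic cell genes were higher (median 0.36, 0.08 on slide 1 and 0.53 on slide 2), 6 when adjusted over the list alone. For macrophages and dendritic cells camera gave adjusted p = 0.0397, and adjusted p = 0.646 with an estimated correlation. Paneth cell genes were higher (median 0.62, 0.51 on slide 1 and 0.79 on slide 2), 5 when adjusted over the list alone, with the antimicrobial genes Ang4 and Pla2g2a at 0.84 ± 0.21 and 0.86 ± 0.23. For Paneth cells camera gave adjusted p = 0.00202, and adjusted p = 0.621 with an estimated correlation. Absorptive enterocyte genes were higher (median 0.35, 0.18 on slide 1 and 0.56 on slide 2), with lactase, Lct, at 0.94 ± 0.25, and so were the circadian clock genes (median 0.28, 0.29 on slide 1 and 0.22 on slide 2). For absorptive enterocytes and circadian clock, in this order, camera gave adjusted p = 7.17e-05 and 0.00290. The adjusted p for absorptive enterocytes and circadian clock was 0.626 and 0.621 with an estimated correlation.

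Mitosis genes were higher, 24 of 27 positive (median 0.20, 0.11 on slide 1 and 0.26 on slide 2), and so were DNA replication genes (median 0.23, 0.12 on slide 1 and 0.29 on slide 2), none passing by either adjustment. For mitosis and DNA replication, in this order, camera gave adjusted p = 0.00156 and 7.55e-05. For mitosis and DNA replication the adjusted p was 0.621 with an estimated correlation. Smooth muscle (median -0.47, with -0.15 and -0.76 on the slides), fibroblast (median -0.43, with -0.25 and -0.54 on the slides), regeneration (median -0.67, with -0.40 and -1.08 on the slides), adipocyte (median -0.42, with -0.33 and -0.58 on the slides), enteric neuron and glia (median -0.18, with -0.06 and -0.33 on the slides) and heat shock genes (median -0.07, with 0.02 and -0.24 on the slides) were lower. For smooth muscle, fibroblasts and stroma, regeneration genes, mesenteric adipocytes, enteric neurons and glia and heat shock, in this order, camera gave adjusted p = 3.08e-07, 2.43e-05, 0.000217, 2.43e-05, 0.00618 and 0.0281. The adjusted p for smooth muscle and the other lists just named was 0.621, 0.621, 0.621, 0.432, 0.621 and 0.621 with an estimated correlation. Among them 6 adipocyte and 2 heat shock genes passed when adjusted over the lists alone, the latter the small heat shock proteins Hspb1 (-1.23 ± 0.23) and Cryab (-0.69 ± 0.16). The p53 targets (-0.01, camera adjusted p = 0.885) and FGF and ERK feedback targets (-0.09, camera adjusted p = 0.0733) did not pass, and Lgr5 had 0.92 ± 0.19, adjusted p = 0.275.

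All 15 list calls were lost with fry (interferon response adjusted p = 0.240) and with an estimated correlation. In the other 15 alternatives 7 were kept throughout, those of interferon response, T cells, Paneth cells, DNA replication, the circadian clock, smooth muscle and fibroblasts. Without 8 Gy saline replicate 2 the medians of T cells (0.39), smooth muscle (-0.22), fibroblasts (-0.23) and absorptive enterocytes (0.12) kept their call and were smaller. Macrophages lost their call in 11 of the 15, the slide as a block (adjusted p = 0.0673) among them. Those of B cells, mitosis and heat shock were lost without 8 Gy saline replicate 1 (adjusted p = 0.0598, 0.127 and 0.0553) and without FGF1/CPP-C replicate 2, where the medians were 0.39, 0.14 and 0.02 (B cells adjusted p = 0.311). Enteric neurons lost theirs without FGF1/CPP-C replicate 2 and, like heat shock and regeneration genes (median -0.42, adjusted p = 0.166), without 8 Gy saline replicate 2 and without the 3 arrays with high antrum transcripts. With the antrum level as a covariate fibroblasts (median -0.16), T cells (0.37) and DNA replication (0.13) kept their calls at smaller medians. Absorptive enterocytes lost theirs with that covariate (median 0.06, adjusted p = 0.195), and they and regeneration genes with antrum and acinar levels as 2 covariates. Adipocytes lost theirs with the series matrix values (adjusted p = 0.313). Of lists not called, FGF and ERK feedback targets were lower without 8 Gy saline replicate 1 (median -0.16, adjusted p = 0.0104) or FGF1/CPP-C replicate 1 (median -0.23, adjusted p = 0.0173), and p53 targets higher without 8 Gy saline replicate 2 (median 0.09, adjusted p = 0.0190) or the 3 arrays (adjusted p = 0.0117). Crypt base stem cells and FGF receptors and ligands were lower without 8 Gy saline replicate 1, and pro-apoptotic genes higher in 6 of the 15. With the slide as a block Tff2 and Gkn3 both passed. Without the 3 arrays with high antrum transcripts, a choice made after the values were seen that leaves 1 residual degree of freedom, 0 genes passed, and without 8 Gy saline replicate 1, 4 did.

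The fourth comparison, 8 Gy FGF1/CPP-C against 8 Gy FGF1, asked how the 2 proteins differed, with the same limit on the segment. The same 2 genes passed of 21759, Tff2 (at least 2.91e+04-fold lower after FGF1/CPP-C, adjusted p = 0.000216 by limma) and Gkn3 (688-fold lower, -9.43 ± 0.40, adjusted p = 0.00411 by limma), and both passed with the slide as a block. As a list, mitosis genes were higher after FGF1/CPP-C, 24 of 27 positive (median 0.36, 0.27 on slide 1 and 0.49 on slide 2), none over all genes and 3 when adjusted over the list alone, with Ube2c and Nek2 at 0.49 ± 0.10 and 0.45 ± 0.10 (limma adjusted p = 0.284 and 0.295). For mitosis camera gave adjusted p = 6.81e-11, and adjusted p = 0.720 with an estimated correlation. An unadjusted p under 0.05 was reached by 1964 genes, 1191 higher and 773 lower, where about 1088 would by chance.

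Genes that did not pass but had the smallest p among those at least 2-fold apart were Paqr9 (2.72 ± 0.21, adjusted p = 0.0616), the water channel gene Aqp8 (4.68 ± 0.46, adjusted p = 0.0886), Slc5a12 (3.60 ± 0.36), Vmn1r132 (at least 2.17-fold higher), Hoxc5 (at least 3.22-fold higher), Kel (at least 5.11-fold lower, adjusted p = 0.0536), B3galt5 (-3.34 ± 0.25, adjusted p = 0.0603) and Slc13a3 (at least 3.67-fold lower). Higher lists were DNA replication (median 0.30, with 0.27 and 0.32 on the slides), T cells (median 0.48, with 0.36 and 0.56 on the slides), interferon response (median 0.34, with 0.54 and 0.07 on the slides), B cells (median 0.80, with 0.22 and 1.67 on the slides), Paneth cells (median 0.46, with 0.45 and 0.45 on the slides), absorptive enterocytes (median 0.24, with 0.37 and 0.11 on the slides) and the circadian clock (median 0.19, with 0.32 and 0.14 on the slides). For DNA replication, T cells and intraepithelial lymphocytes, interferon response, B cells, Paneth cells, absorptive enterocytes and circadian clock, in this order, camera gave adjusted p = 1.39e-09, 1.06e-05, 0.000213, 0.000256, 0.0344, 0.00379 and 0.00216. For DNA replication and the other lists just named the adjusted p was 0.720 with an estimated correlation. None of their genes passed over all genes, and only the clock list had any when adjusted over the list alone, 4, among them Nr1d1, a repressor of the core clock (1.40 ± 0.20). In Paneth cells the examples were opposed, Pla2g2a at 0.72 ± 0.23 and Reg3g at -1.53 ± 0.37.

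Lower lists were enteroendocrine cells (median -0.21, with -0.13 and -0.28 on the slides), with 3 when adjusted over the list alone, among them the peptide hormone gene Pyy (-1.62 ± 0.30) and the granin gene Chgb (-0.63 ± 0.09), and fibroblasts (median -0.24, with -0.33 and -0.21 on the slides), smooth muscle (median -0.22, with -0.09 and -0.31 on the slides), regeneration genes (median -0.48, with -0.42 and -0.23 on the slides), enteric neurons and glia (median -0.15, with -0.00 and -0.33 on the slides) and endothelium (median -0.08, with -0.03 and -0.22 on the slides), with none. For enteroendocrine cells, fibroblasts and stroma, smooth muscle, regeneration genes, enteric neurons and glia and endothelium, in this order, camera gave adjusted p = 0.0231, 0.00170, 0.00638, 0.0184, 0.0231 and 0.0488. For enteroendocrine cells and the other lists just named the adjusted p was 0.720 with an estimated correlation. The regeneration list holds Anxa10, also an antrum marker (-4.96 ± 1.60), and antrum transcripts were high in FGF1 replicate 1. The p53 target list had a median of -0.02 (camera adjusted p = 0.905).

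Of the 14 list calls only those of mitosis, DNA replication and T cells were kept in all 15 alternatives, though without the 3 arrays with high antrum transcripts all 14 were. Fry (adjusted p = 0.266 for mitosis and for DNA replication) and the estimated correlation, which are not among the 15, ended all 14 calls. The slide as a block ended that of Paneth cells (adjusted p = 0.0676), which was lost in 7 of the 15, as endothelium was in 9. With the antrum level as a covariate those of absorptive enterocytes (median 0.03, adjusted p = 0.942), regeneration genes (median -0.01, adjusted p = 0.697), smooth muscle (median -0.08), fibroblasts (-0.10), Paneth cells (0.29) and enteric neurons (-0.10) were lost. With the acinar level as another covariate it was those of interferon response (median 0.08, adjusted p = 0.886), enterocytes, regeneration genes, fibroblasts, the clock (median 0.14) and endothelium (median -0.25, further from 0 than in the main fit). Without FGF1/CPP-C replicate 1 interferon response (median 0.15, adjusted p = 0.110), fibroblasts, the clock, regeneration genes and enteroendocrine cells lost theirs, and without replicate 2 B cells (median 0.35, adjusted p = 0.293) and enteric neurons did. Enterocytes and regeneration genes lost theirs without FGF1 replicate 1, and smooth muscle, enteroendocrine cells and enteric neurons without FGF1 replicate 2. The enteroendocrine call was also lost without either 8 Gy saline array. Without the 3 arrays with high antrum transcripts 0 genes passed, and without FGF1 replicate 1, FGF1 replicate 2 or FGF1/CPP-C replicate 1, 5, 4 and 5 did.

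**Figure D3:**
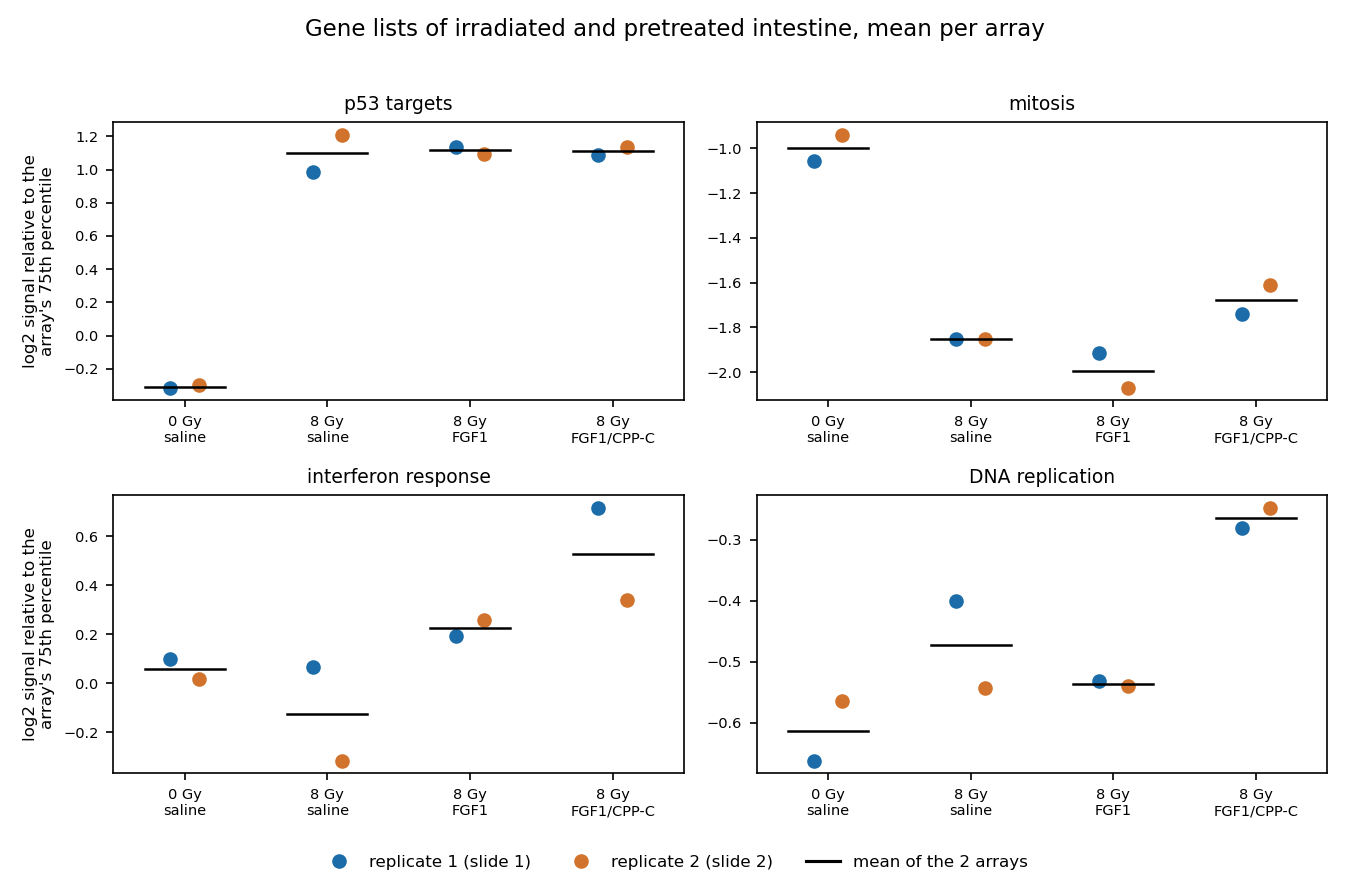
Mean normalised signal per array (y axis, log2 signal relative to the array's 75th percentile) of the p53 target, mitosis, interferon response and DNA replication lists in the 4 groups (x axis); points are single arrays coloured by replicate and slide, and bars are the mean of the 2 arrays. The interferon mean is 0.19 to 0.72 in the 4 pretreated arrays and -0.32 to 0.10 in the 4 saline arrays.

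The 89 genes that changed with irradiation alone were followed in this comparison, which shares no array with the first. The 21 that had fallen had a median of 0.37 (camera p = 9.52e-10, p = 0.0329 with an estimated correlation), and the 68 that had risen 0.01 (camera p = 0.963). These p-values are not adjusted. Among the 21 are the mitosis genes that had passed in the first comparison, such as Ccnb1, Ccnb2 and Nek2. Their shift is therefore not separate from that of the mitosis list given above. Across the 89 genes, which are not independent replicates, the 2 sets of fold changes had r = -0.41 and rho = -0.38, and 51 had opposite signs.

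Against 0 Gy saline, 195 genes changed in 8 Gy FGF1, 133 higher and 62 lower, and 438 in 8 Gy FGF1/CPP-C, 270 higher and 168 lower, of 21738 and 21739 tested. With the slide as a block 76 and 176 changed. Gdf15 rose by 5.70 ± 0.30 and 6.01 ± 0.30 (limma adjusted p = 0.00535 and 0.00276), Phlda3 by 4.01 ± 0.22 and 3.75 ± 0.22, and Saa3, an acute-phase protein gene, by 5.15 ± 0.45 and 5.77 ± 0.45. Cdkn1a passed in both, by 1.01 ± 0.12 and 1.02 ± 0.12 (limma adjusted p = 0.0335 and 0.0247), and Mki67 fell in FGF1 (-0.93 ± 0.12, adjusted p = 0.0389). In FGF1, Cyp1a1, Sfrp5 and the mast cell protease gene Mcpt4 fell (-2.64 ± 0.19, -2.28 ± 0.18 and -1.88 ± 0.24). In FGF1/CPP-C, Slc5a12 was at least 17.2-fold higher, and Tff2 (at least 4.18e+04-fold), Gkn3 (-10.04 ± 0.40), Wfdc18 (-9.09 ± 1.11) and the water channel gene Aqp5 (at least 525-fold) were lower. Of 30 p53 targets, 16 and 17 rose, and 23 in each when adjusted over the list alone (medians 1.27 and 1.28, camera adjusted p = 8.65e-26 and 3.75e-20, adjusted p = 0.119 and 0.188 with an estimated correlation). Of 27 mitosis genes, 11 and 8 fell, and 26 and 20 when adjusted over the list alone (medians -0.93 and -0.57, camera adjusted p = 2.96e-25 and 2.94e-13, adjusted p = 0.409 and 0.529 with an estimated correlation).

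All 3 irradiated groups were set against the same 0 Gy saline arrays. Of the 68 genes higher in 8 Gy saline, 67 were also higher in FGF1 and 65 in FGF1/CPP-C, where independent lists would share 0.417 and 0.849, a value that leaves out the shared controls. The fold changes of saline and FGF1 had r = 0.777 across genes and a covariance of 0.105, against 0.497 and 0.0428 for simulated unchanged groups. Those of saline and FGF1/CPP-C had r = 0.473, not above the simulated 0.498, and a covariance of 0.0876 against 0.0427. The 2 control arrays were not split, since each part would keep only 1. The simulation covers the shared controls only at the fitted spread, so part of any excess over it may still come from them. Without 0 Gy saline replicate 1 or 2, 0 and 0 genes passed in FGF1 and 18 and 11 in FGF1/CPP-C, without FGF1 replicate 1 or 2, 0 and 1 passed in FGF1, and without FGF1/CPP-C replicate 1 or 2, 27 and 15 passed in FGF1/CPP-C. The share of the calls that were higher was 68.2% in FGF1, 52.7% with normexp background correction and 57.3% with the series matrix values, and in FGF1/CPP-C it was 61.6%, and 49.7% with the series matrix values.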

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

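Deviations from the group means correlated between groups with r from -0.519 to 0.536. The arrays with high antrum transcripts were replicate 1 in 0 Gy saline and FGF1 (r = 0.536 between them). In 8 Gy saline it was replicate 2 (r = -0.519 and -0.364 with those groups). These values may follow the antrum transcripts, so they cannot exclude an effect of the replicate number, which is the slide. With it as a block, 37 genes changed in 8 Gy saline against 0 Gy saline in place of 89, 76 in FGF1 against 0 Gy saline in place of 195 and 176 in FGF1/CPP-C against 0 Gy saline in place of 438, and the counts of 0, 2 and 2 in the other 3 comparisons did not move. Leaving out the 3 arrays with high antrum transcripts and using antrum or acinar levels as covariates were chosen after seeing the data. In what follows, 0 Gy stands for 0 Gy saline.

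Counts of genes moved as follows. For 8 Gy saline against 0 Gy (89), there were 136 with normexp, 32 with no filter on dim probes, 0 in a fit to the 2 groups alone, 147 with trend and robust, 248 by unadjusted p and 2-fold, 0 without the 3 arrays and 0 with 2 covariates, and from 0 to 43 without single arrays. For FGF1 against 8 Gy saline (0), there were 2 with the mean of probes, 52 by unadjusted p and 2-fold, and from 0 to 1 without single arrays. For FGF1/CPP-C against 8 Gy saline (2), there were 9 with quantile normalisation, 4 with normexp, 0 with the series matrix, 5 with no filter on dim probes, 1 with probes well above background on all 8 arrays, 7 with the mean of probes, 0 in the 2 groups alone, 327 by unadjusted p and 2-fold, 0 without the 3 arrays, 14 with the antrum covariate, 0 with 2 covariates, and from 2 to 4 without single arrays. For FGF1/CPP-C against FGF1 (2), these were 12, 10, 0, 9, 1, 9, 0, 250, 0, 15 and 0, with 8 by trend and robust, and from 2 to 5 without single arrays. For FGF1 against 0 Gy (195), there were 298 with normexp, 3 in the 2 groups alone, 366 with trend and robust, 350 by unadjusted p and 2-fold, 0 without the 3 arrays, 0 with 2 covariates, and from 0 to 172 without single arrays. For FGF1/CPP-C against 0 Gy (438), there were 259 with no filter on dim probes, 10 in the 2 groups alone, 700 with trend and robust, 658 by unadjusted p and 2-fold, 245 by adjusted p and 2-fold, 0 without the 3 arrays, 170 with the antrum covariate, 5 with 2 covariates, and from 11 to 848 without single arrays. The fits with fewer arrays or more terms have fewer residual degrees of freedom, and an array left alone in its group is assumed to vary like the other groups. For the other settings the cause was not tested.

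With an estimated correlation 0 lists were called in each of the first 4 comparisons, and with fry 2, 0, 0 and 0, where camera called 13, 15, 15 and 14. Without single arrays camera called 11 to 16, 12 to 20, 12 to 22 and 9 to 13, and for FGF1 against 8 Gy saline 6 without the 3 arrays and 5 with 2 covariates.

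Some values turned sign, or camera's direction did, and the cause was not tested. Trim71 in FGF1 against 8 Gy saline was 0.073 with no filter on dim probes, and Egr1 0.80 without the 3 arrays. Without single arrays the enterocyte median in 8 Gy saline against 0 Gy ranged from -0.26 to 0.30. In FGF1 against 8 Gy saline the medians ranged from -0.35 to 0.25 for crypt stem cells, -0.14 to 0.12 for p53 targets, -0.44 to -0.020 for smooth muscle, -7.61 to -0.32 for acinar cells, -0.43 to 0.10 for fibroblasts, -0.61 to 0.24 for regeneration genes and -0.13 to 0.42 for enterocytes. Only camera's direction turned, and not the median's sign, for crypt stem cells and p53 targets without 8 Gy saline replicate 1, for smooth muscle and acinar cells without 8 Gy saline replicate 2 and for enterocytes without FGF1 replicate 2 (0.012). Without 8 Gy saline replicate 2 the medians of fibroblasts (0.10), regeneration genes (0.24) and enterocytes (-0.13) turned. Medians of called lists also turned with no turn in camera's direction: in that comparison neutrophils (-0.079), macrophages (-0.0021), junction genes (-0.015) and glycolysis and hypoxia (-0.0019) without that array, and enterocytes (-0.015), macrophages (-0.0099) and neutrophils (-0.075) without the 3 arrays. The others were regeneration genes in 8 Gy saline against 0 Gy (-0.17 without 8 Gy saline replicate 2), heat shock in FGF1/CPP-C against 8 Gy saline (0.024 without FGF1/CPP-C replicate 2), and enterocytes (-0.00077) and regeneration genes (0.040) in FGF1/CPP-C against FGF1 with 2 covariates. Without the 3 arrays smooth muscle was 0.046, fibroblasts 0.014 and regeneration genes 0.042. With 2 covariates the acinar median was 0.084. In FGF1/CPP-C against 8 Gy saline the p53 median ranged from -0.059 to 0.091 without single arrays, and was 0.091 without the 3 arrays and 0.11 with 2 covariates. The genes that rose with irradiation had 0.089 in FGF1/CPP-C against FGF1 with the antrum covariate in place of 0.0075, where again only camera's direction turned. Of 66 values of single genes that passed, none turned sign where refitted. Still passing were 42 with the block, 28 with no filter on dim probes, 7 in the 2 groups alone, 52 with the antrum covariate, 2 with 2 covariates and 0 without the 3 arrays. Without single arrays 7 to 47 passed, with 8 and 7 without 0 Gy replicate 1 and 2. With the series matrix 46 of 54 with values passed, and with probes well above background on all 8 arrays 52 of 53. Probes near background limit the measured folds, and genes not well above background have bounds only.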

Other observations

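The gene lists of the next paragraph and the Hox and Brunner gland lists were chosen after their values had been seen, and their p-values are adjusted over these lists. Of the tests of explanations, only those of stomach or pancreas RNA in 8 Gy saline replicate 2 and of pretreatment with either protein on the interferon list were chosen before their results were seen.

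Acute-phase genes, which encode proteins secreted in inflammation, had a median of 0.55 in FGF1 against 8 Gy saline, 0.51 on slide 1 and 0.69 on slide 2 (camera adjusted p = 7.56e-09, adjusted p = 0.0832 with an estimated correlation), and 0.42 in FGF1/CPP-C against 8 Gy saline (camera adjusted p = 0.0334, adjusted p = 0.236 with an estimated correlation). Against 0 Gy saline, 4 of the 11 measured rose in each pretreated group, with medians of 1.23 and 0.92, and the list was also higher in 8 Gy saline (median 0.40, camera adjusted p = 0.00114, adjusted p = 0.365 with an estimated correlation), with no gene passing. Alpha-defensins, antimicrobial peptides of Paneth cells, were positive in 11 of 11 in FGF1/CPP-C against 8 Gy saline (median 0.94, camera adjusted p = 1.16e-08, adjusted p = 0.181 with an estimated correlation) and against FGF1 (median 0.63, camera adjusted p = 8.69e-08, adjusted p = 0.217 with an estimated correlation), none passing over all genes. They were also positive in 11 of 11 in FGF1 against 8 Gy saline (median 0.30, -0.01 on slide 1 and 0.57 on slide 2, camera adjusted p = 0.000781, adjusted p = 0.706 with an estimated correlation). These near-identical genes can share probes, so they do not count as separate measurements. The B cell median was -0.35 in FGF1/CPP-C replicate 2 and -2.72 in replicate 1.

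Stomach antrum transcripts were high in 3 arrays and pancreatic acinar transcripts in 2 of them, while FGF1/CPP-C replicate 1 had intermediate acinar transcripts (median -1.25, with Amy2a5 at 0.76 against -6.95 in replicate 2) and low antrum ones. Between the 2 arrays of 0 Gy saline the antrum median differed by 4.75, and by up to 5.96 within a group, which argues against irradiation or pretreatment, and the gap between the slides was -6.54, an overlap, which argues against the slide. Tissue of the neighbouring stomach or pancreas in the sample is a candidate explanation: 100% of the measured acinar genes lay over 2 log2 units apart in 1 direction in that pair, while the enterocyte median differed by 0.221. The abundant enzyme genes Amy2a5, Try4 and Ctrb1 had 7.70, 7.34 and 7.10 in replicate 1 against -5.94, -6.95 and -2.43 in replicate 2. FGF1 replicate 1 had high antrum markers with an acinar median of -4.79, so pancreas is no candidate there.

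The Brunner gland list was low in both FGF1/CPP-C arrays, with a median of -5.76 against FGF1, though Egf (-5.36 and -5.29), Pigr (8.10 and 8.01) and Slc12a7 (2.74 and 2.69) lay within the range of the other arrays. Loss of signal in these arrays is argued against by the absorptive enterocyte median of 0.24. A segment further from the stomach may have been sampled, and Hox genes, a list chosen after the values were seen, were positive in 13 of 13 (median 0.34, 0.45 on slide 1 and 0.17 on slide 2, camera adjusted p = 6.43e-07, adjusted p = 0.119 with an estimated correlation). The segment lists, drawn up in advance but made part of this test only after the Hox result was seen, were not called. The proximal list had a median of 0.20, where the test asked for a fall (camera adjusted p = 0.323), and the distal list 0.14 (camera adjusted p = 0.283). The distal marker Pyy had -1.62 ± 0.30. A shift within the proximal small intestine need not lower the proximal list, so these lists do not decide. The segment and repression by FGF1/CPP-C cannot be told apart, since both arrays of that group and no other show the low levels of Tff2 and Gkn3. In the arrays of the other groups Tff2 was 8.15 to 8.99 and Gkn3 7.18 to 8.37. The design text names jejunum, and whether the high or the low levels belong to that segment was not tested. The same limit holds for other differences between FGF1/CPP-C and the other irradiated groups.

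Interferon response genes were higher in both pretreated groups than in irradiated saline. The list mean of the lowest pretreated array lay 0.0967 above that of the highest saline array, as an effect of pretreatment with either protein would require. However, no gene passed over all genes. The calls were also lost with an estimated correlation (adjusted p = 0.801 and 0.621) and with fry (adjusted p = 0.991 and 0.240). Stomach or pancreas RNA in 8 Gy saline replicate 2 is a possible cause of part. Without that array 48.0% of the median stayed in FGF1 and 69.6% in FGF1/CPP-C. This shows that the array was low, but not that such RNA made it low. In 0 Gy saline the list mean was 0.10 in replicate 1, also high in antrum and acinar transcripts, and 0.02 in replicate 2. In FGF1 it was 0.19 in replicate 1, high in antrum transcripts, and 0.26 in replicate 2. Antrum and acinar levels as 2 covariates left medians of 0.40 and 0.38 (camera adjusted p = 3.67e-11 and 6.28e-08). That fit was chosen after seeing the data and has fewer residual degrees of freedom than the main fit. Both covariates are high in only a few arrays, 8 Gy saline replicate 2 among them. The fit therefore does not decide whether such RNA is the whole cause. More immune cells could also contribute, the macrophage median being 58.2% of the interferon median in FGF1, the T cell median 32.6% and the B cell median -7.72%. In FGF1/CPP-C these were 57.4%, 109% and 196%. However, without 8 Gy saline replicate 2 the macrophage medians were -0.00 and 0.07. The B cell share in FGF1/CPP-C rested on replicate 2. Without it the interferon median was 0.84, and those of macrophages, T cells and B cells were 0.29, 0.52 and 0.39. How much of the shift is due to these 2 explanations, to pretreatment or, in FGF1/CPP-C, to the segment sampled cannot be told apart with 2 arrays per group.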
